A study of Mus musculus with 14 samples.

How the data were processed

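H3K27ac ChIP-seq was analysed in 8 immunoprecipitated libraries from passaged mouse embryonic fibroblasts, with 2 libraries each for cells without virus, with rtTA, with rtTA and inducible Ascl1, and with rtTA and inducible Myod1. The series lists 14 samples, and its 6 input libraries were not analysed here. Per the labels, cells were cultured with 2 µg/ml doxycycline for 48 h. The deposited table gives 26500 regions of exactly 1000 bp with 1 value per library. The name of the table reads RPKM, and since every region is 1 kb long the authors' RPKM and RPM are the same number, rounded by the authors to 2 decimals. Region names call them merged peaks with the letters A and M, but which peaks were merged, how they were called and how reads were extended are not given in the sources used here. The letters can be read as Ascl1 and Myod1. If the regions were chosen from peaks of these factors, shares of regions higher or shared do not hold for acetylated sites in general. The name of the deposited table can be read as without the coding sequences of Ascl1 and Myod1, and of 5 skipped region numbers 4 lie next to regions assigned to these genes. Per the submitters' processing notes, Bowtie2 2.1.0, DiffBind 1.16.3 and build mm10 were used upstream.

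In every library all values were whole multiples of 1 step, within 0.0055 RPM, so whole reads were recovered by dividing by that step. The total implied by the step was 28.7 and 16.2 M reads without virus, 4.4 and 8.2 M with rtTA, 18.4 and 25.7 M with Ascl1, and 15.3 and 15.1 M with Myod1. A count of 3 reads, taken as the floor of a library, corresponds to 0.105 to 0.682 RPM. Floors cover counting error only, because reads without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 3.28 without virus, 2.78 with rtTA, 21.16 with Ascl1 and 10.34 with Myod1, so each library counted as a replicate.

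Regions were placed on the genes of the reference annotation GRCm38.p6, the same assembly as mm10, which was used without strand or sequence. Each region went to the protein-coding gene that contains its centre or whose body lies nearest, at any distance, which gave 26479 regions a gene and left 21 on unplaced scaffolds. A region was called a gene-end region if its centre lay within 1 kb of either end of any protein-coding gene, since starts could not be told from the opposite ends. Starts inside a longer annotated gene span therefore count as gene body. Gene-end regions numbered 5202, gene-body regions 13235 and regions between genes 8042. Both rules replaced the nearest transcription start of the design after the annotation was seen to have no strand. An assigned gene is the nearest one and has not been shown to be regulated by the region.

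Values were used as deposited, without further scaling between libraries, on the scale log2(RPM + 1). The added 1 makes log2 fold changes at weak regions smaller than the ratio of the means. The 25657 regions with a mean of at least 1 RPM over the 8 libraries were tested, and 843 were left out. A linear model with 1 mean per group was fitted to all 8 libraries in limma 3.58.1 (R 4.3.3) with an intensity trend, so that the 4 groups share an estimate of the spread. P-values are two-sided and adjusted by Benjamini-Hochberg over the regions, with a threshold of 0.05 and no minimum fold. The comparisons were Ascl1 with rtTA, Myod1 with rtTA, Ascl1 with Myod1, and rtTA with no virus, with each factor against no virus as an alternative control.

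Genes named in the text were chosen by a rule. For the first 3 comparisons it takes the 8 genes with the largest rise and the 8 with the largest fall among called regions within 50 kb of a gene, and for the controls the 3 and 3 largest. It adds up to 4 genes per list with the largest absolute change at any distance, and the regions nearest Ascl1 and Myod1. The latter were read only among the tested regions. A gene of a list counts as risen if at least 1 of its regions rose and none fell, as fallen in the opposite case, and as mixed if both occurred. A gene with more regions thus has more occasions to be counted, so counts of genes cannot be set against shares of regions. The share of all genes risen or fallen is not given here. The 16 lists were skeletal muscle, myogenic regulators, neuronal structure and synapse, proneural regulators, Notch pathway, fibroblast identity and extracellular matrix, smooth muscle and actin cytoskeleton, cell cycle, interferon response, macrophage and blood cells, endothelial, epithelial, cartilage with bone and fat, glia and neural crest, heart regulators, and ubiquitously used genes. They hold 517 genes, of which 6 are in 2 lists, 513 are in the annotation and 359 have a region. Lists were tested with camera in limma against all other regions, with a preset correlation of 0.01 and with an estimated correlation beside it, adjusted over the 16 lists within a comparison. Regions with a group at 0 in both libraries numbered at most 2 per list, and setting them to their bound moved 3 of 96 list medians, by at most 0.05. Groups, comparisons, tests, lists, the rule and most of the alternatives were fixed before the data were examined.

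The overlap of the regions higher with both factors was set beside the product of the shares of both lists and the correlation of the fold changes beside that in 20 simulations of unchanged groups that share the rtTA libraries. Alternatives were other offsets, filters and scalings (centring each library on its median, quantile normalization), a replicate term, other spread models, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, other controls, other gene assignments, equal depth by thinning, and leaving out each library. The model was tested on simulated data with 100 regions changed 2-fold and 100 changed 4-fold in each of the 4 comparisons. It recovered 27% to 36% of the 4-fold changes and 0% to 2% of the 2-fold ones, with 3 to 5 false calls. Far more regions were called in the real comparisons, where the adjusted threshold is laxer, so these shares hold only for few changed regions. Tests of E-box content and a GC correction needed genome sequence, which was not used here, and an input correction needed input values, which were not analysed here. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.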

Results

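H3K27 acetylation (H3K27ac), a histone mark of active promoters and enhancers, was measured by ChIP-seq in mouse embryonic fibroblasts (MEFs). The cells carried no virus, the reverse tetracycline transactivator alone (rtTA), or rtTA with a doxycycline-inducible, flag-tagged Ascl1 or Myod1. Ascl1 is a basic helix-loop-helix factor that turns fibroblasts towards neurons, and Myod1 is the related factor that turns them into muscle. The series design places every group at 48 h after doxycycline (2 µg/ml). The treatment text common to all samples does not state separately whether cells without virus received doxycycline. Each of the 4 groups had 2 immunoprecipitated libraries, and the deposited table gave their signal in 26500 regions of 1000 bp, of which 25657 were tested. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

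The steps of the deposited values corresponded to 28.7 and 16.2 M reads for the libraries without virus, 4.4 and 8.2 M for rtTA, 18.4 and 25.7 M for Ascl1 and 15.3 and 15.1 M for Myod1. The regions held 8.6% and 9.7% of the reads without virus, 19.2% and 16.1% with rtTA, 27.4% and 23.0% with Ascl1, and 16.2% and 15% with Myod1. The mean of the library medians was 2.35 ± 0.17 RPM (SD, n = 2) without virus, 3.58 ± 0.0849 RPM with rtTA, 8.52 ± 1.53 RPM with Ascl1 and 4.87 ± 0.707 RPM with Myod1. Replicates correlated across regions at Pearson's r of 0.94 without virus, 0.92 with rtTA, 0.80 with Ascl1 and 0.83 with Myod1, and regions are not independent replicates. The groups also differed in where the signal lay. The median within 1 kb of a gene end was 7.31 and 5.65 times the median between genes in the rtTA libraries, 1.77 and 1.85 times without virus, 1.81 and 1.02 times with Ascl1, and 1.08 and 0.93 times with Myod1.

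**Figure D1:**
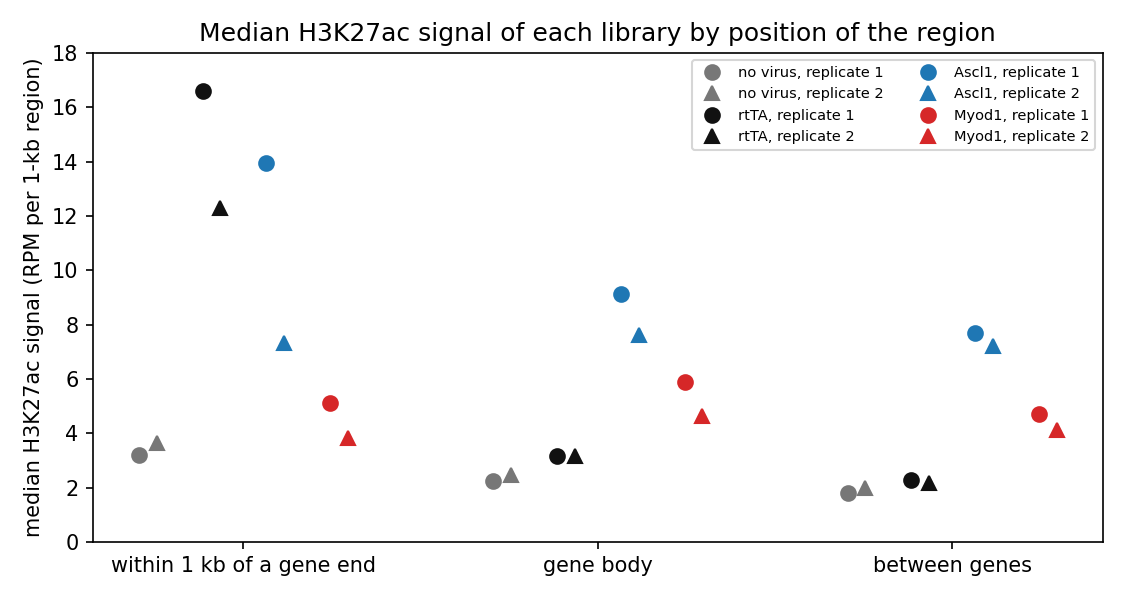
Median H3K27ac signal (y axis, RPM per region of 1 kb) of each of the 8 libraries at regions within 1 kb of a gene end, in gene bodies and between genes, with circles for replicate 1 and triangles for replicate 2. At gene ends the medians were 16.6 and 12.31 RPM in the rtTA libraries and 13.94 RPM in Ascl1 replicate 1, above the other 5 libraries, which lay between 3.21 and 7.32 RPM.

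Ascl1 was compared with rtTA alone to ask where acetylation changes when the neuronal factor is induced. Among the genes named by the fixed rule, Olfml2b rose most, in its gene body (build mm10, chromosome 1, 170655260 to 170656259), from 0.700 ± 0.297 to 26.0 ± 0.396 RPM (SD, n = 2 libraries per group here and below). Its log2 fold change was 4.00 (SE 0.31, limma adjusted p = 0.000178). A region 2.64 kb from Chat (chromosome 14, 32405064 to 32406063), which encodes the enzyme that makes acetylcholine, rose from 0.225 ± 0.318 to 15 ± 1.83 RPM. A region 4.37 kb from Tnr (chromosome 1, 159518863 to 159519862), the gene of the neural matrix protein tenascin-R, held no reads in either rtTA library and 11.8 ± 0.368 RPM with Ascl1. That is at least 17.3-fold higher, with 3 reads in the shallower rtTA library as the floor. The other genes with the largest rises were Rps6ka5, Hivep3, Padi2, Agbl1 and Palmd, with log2 fold changes of 3.68 to 3.80.

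Genes of neuronal structure and synapse rose with Ascl1. Of the 39 genes with a region, 33 rose and the other 6 had no region past the threshold. In regions, 86 of 112 were higher, and 88 adjusted over the list alone, while 45.8% of all regions were higher. With each library centred on its median, 18 of the 39 genes rose, 5 fell and 5 were mixed. Syt1, the calcium sensor of synaptic vesicles, went from 0.470 ± 0.0283 to 15.2 ± 0.502 RPM in its gene body (chromosome 10, 108929979 to 108930978; log2 fold change 3.46, SE 0.32, limma adjusted p = 0.000178). The transmembrane gene Dner went from 0.285 ± 0.233 to 11.4 ± 2.85 RPM, the stathmin gene Stmn4 from 1.06 ± 0.212 to 17.6 ± 1.58 RPM, and the complexin gene Cplx2 from 0.680 ± 0.962 to 12.1 ± 1.74 RPM. The median of the list was 1.45, which is 0.68 above the median of all regions (camera adjusted p = 1.18e-05, and adjusted p = 0.0634 with an estimated correlation). In rtTA against no virus, 6 regions of this list were higher and 1 was lower. Against the libraries without virus, 97 regions were higher with Ascl1 and the list stood 0.37 above the median of all regions (camera adjusted p = 0.00187, and adjusted p = 0.182 with an estimated correlation).

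Proneural regulators, the transcription factors of neuronal commitment, rose at 20 of 27 genes with Ascl1, and 2 more genes had both risen and fallen regions. In regions, 83 of 126 were higher and 2 lower, and 86 and 2 adjusted over the list alone. The zinc finger gene Myt1l rose in its gene body (chromosome 12, 29916900 to 29917899) from 0.790 ± 1.12 to 19.1 ± 1.05 RPM (log2 fold change 3.65, SE 0.41, limma adjusted p = 0.000194). The repressor gene Zbtb18 rose from 0.710 ± 0.368 to 19.1 ± 3.59 RPM (log2 fold change 3.56, and 2.09 against no virus, where it held 3.76 RPM) and the homeobox gene Prox1 from 0.245 ± 0.346 to 8.52 ± 1.93 RPM. The region assigned to Bcl11a, with a log2 fold change of 3.06, lies 779 kb from the gene. The list stood 0.61 above the median of all regions (camera adjusted p = 0.000785, and adjusted p = 0.805 with an estimated correlation). Of its 126 regions, 22 were higher in rtTA than without virus and 2 were lower. After centring, 35 proneural and 38 neuronal regions were higher with Ascl1, and 13 and 12 lower. In the Notch pathway, 18 of 23 genes rose and 1 was mixed (45 regions of 96 higher and 1 lower, and 45 and 1 adjusted over the list alone; camera adjusted p = 0.567), which centring turned to 10 higher and 18 lower. Of these Notch regions, 17 were higher in rtTA than without virus. A region 24.1 kb from the ligand gene Dll1 went from 0.700 ± 0.297 to 12.3 ± 0.721 RPM, and a region 0.56 kb from Dll3 from 1.52 ± 0.431 to 13.4 ± 1.12 RPM.

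Regions of other lineages were also among those that rose with Ascl1, though none of the next 3 lists passed camera and 45.8% of all regions were higher. Of 53 skeletal muscle genes with a region, 38 rose and 2 fell (61 regions of 101 higher and 2 lower, and 62 and 3 adjusted over the list alone). Tnnt2, a troponin gene, went from 0.820 ± 0.127 to 16.9 ± 0.601 RPM at a region 0.195 kb from its end, and Tnnt3 from 1.85 ± 1.33 to 17.2 ± 0.707 RPM. Of 18 myogenic regulators, 16 rose (33 regions of 59 higher, and 34 adjusted over the list alone), with Mef2a at a log2 fold change of 2.88 and Mef2d at 2.70. Of 44 fibroblast identity and matrix genes, 23 rose, 2 fell and 3 were mixed (74 regions of 190 higher and 7 lower, and 73 and 6 adjusted over the list alone). A region 12.1 kb from the tenascin gene Tnc rose by 2.58 and a region 14.9 kb from Serpine1 by 2.46 on the log2 scale. Relative to all regions these lists stood at 0.29 for muscle (camera adjusted p = 0.202), 0.27 for myogenic regulators (adjusted p = 0.457) and -0.10 for fibroblast genes (adjusted p = 0.667). With each library centred on its median the direction of these 3 lists turned, to 16 regions higher and 21 lower for muscle, 5 and 12 for myogenic regulators and 10 and 61 for fibroblast genes. In rtTA against no virus, 8, 11 and 28 of their regions were higher.

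Of 18 ubiquitously used genes, 4 fell, 1 was mixed and 13 had no region past the threshold (4 regions of 33 higher and 7 lower; adjusted over the list alone 2 were higher and none of the 7 lower ones passed). Centring turned these to 22 regions lower and 0 higher, with 17 of the 18 genes fallen, and quantile normalization to 9 lower and 0 higher. The median of the list was 0.89 below that of all regions (camera adjusted p = 0.000168, and adjusted p = 0.805 with an estimated correlation). The call was lost without regions near gene ends (adjusted p = 0.0621), and against no virus (adjusted p = 0.768). Irs2 and Irf2bp2, the genes with the largest falls, dropped from 37.0 ± 22.3 to 6.44 ± 8.78 RPM and from 38.7 ± 17.6 to 7.54 ± 10.1 RPM at gene ends. Both held only 0.035 ± 0.0495 RPM without virus, and against those libraries their log2 fold changes with Ascl1 were 1.99 and 2.18. All 12 named falls lost their call without rtTA replicate 1 (adjusted p from 0.107 for Rbbp6 to 0.352 for Rplp0), 9 of them also without Ascl1 replicate 2 and 6 without rtTA replicate 2. Without rtTA replicate 1 the folds kept most of their size, such as Irs2 (-2.44 against -3.08), Rbbp6 (-2.60 against -2.89) and Hspa8 (-1.55 against -1.64), except Rplp0 (-0.73 against -1.53). Without Ascl1 replicate 2 they shrank, such as Gas1 (-0.87 against -3.00) and Fasn (-0.88 against -2.83). Against no virus all 12 had a positive fold change, 7 of them past the threshold.

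In limma, 11754 regions were higher and 1068 lower with Ascl1 than with rtTA alone, and the median log2 fold change of all regions was 0.77. The split depended on scaling, since calls were 91.7% higher as deposited, 30.5% higher with each library centred on its median (which lowers every log2 fold change by 1.05) and 51.4% higher after quantile normalization. In all 3 scalings, 3001 regions were higher and 1019 lower. Centring moves lower regions further down, so it could hardly cost their calls and does not test them. The lower regions depended on single libraries and on the control, with 62 lower without rtTA replicate 1, 134 without Ascl1 replicate 2, 2610 without Ascl1 replicate 1 and 90 against no virus, and only 32 were lower against both controls. The counts of 90 and 32 hold as deposited only. Against no virus, 4628 regions were lower and 1525 higher after centring, and 2990 and 2798 after quantile normalization. Of the 67 named rises, 56 stayed past the threshold after centring and 66 also rose against no virus. The exception was the heart regulator Gata6.

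**Figure D2:**
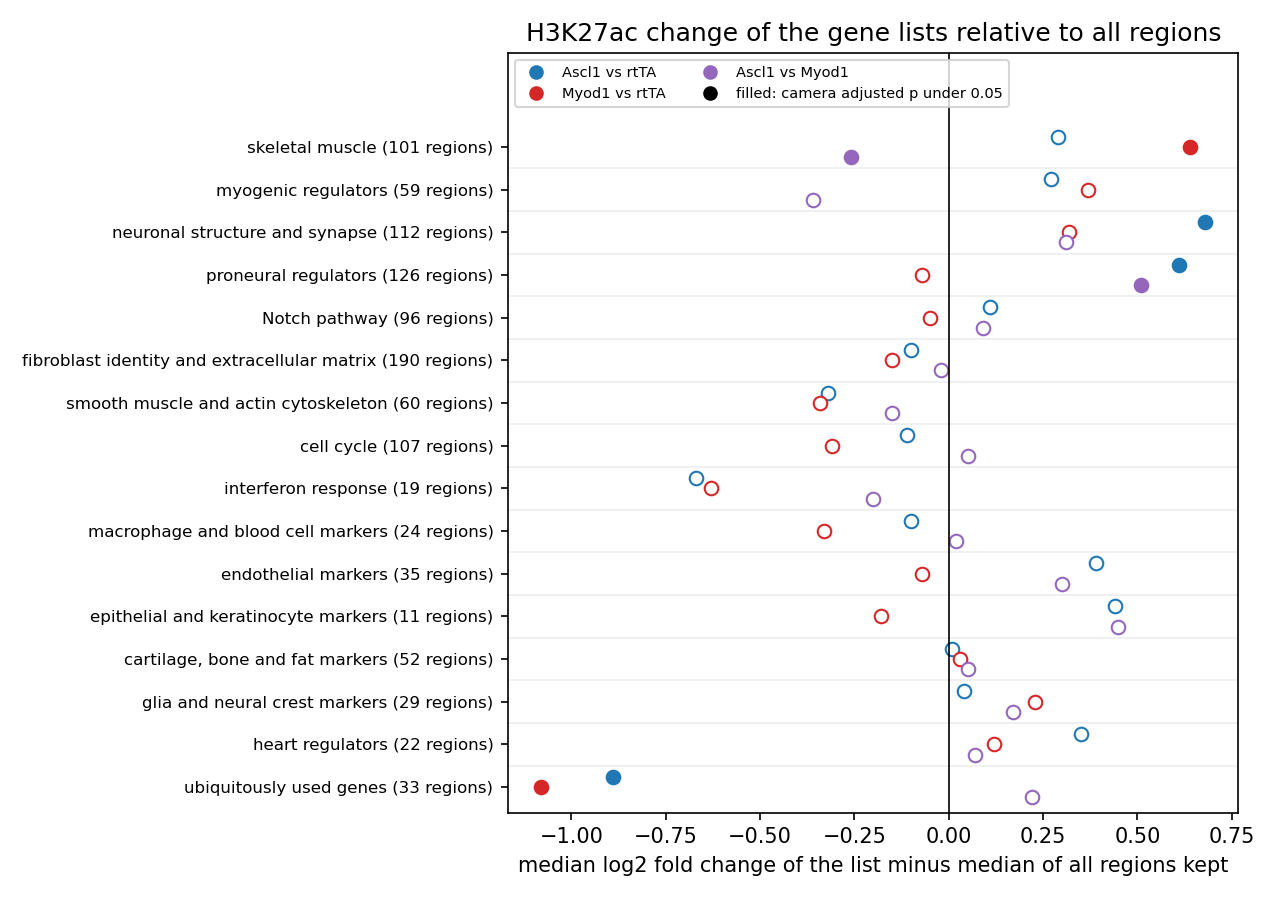
Median log2 fold change of each of the 16 gene lists minus the median of all regions (x axis, log2 units) in 3 comparisons, with filled points where the camera adjusted p with the preset correlation was under 0.05. The neuronal list stood at 0.68 with Ascl1, the muscle list at 0.64 with Myod1, and the ubiquitously used genes at -0.89 and -1.08 against rtTA.

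Myod1 was compared with rtTA to find the regions where the muscle factor changes acetylation, and whether neuronal genes are among them. Muscle genes rose, with 36 of 53 genes of the skeletal muscle list risen, 5 fallen and 1 mixed. In regions, 54 of 101 were higher and 7 lower, and 57 and 7 adjusted over the list alone. Smyd1, which encodes a methyltransferase needed for sarcomere assembly, rose from 0.225 ± 0.318 to 11.1 ± 0.467 RPM at a region 0.316 kb from its end (chromosome 6, 71262098 to 71263097; log2 fold change 3.33, SE 0.33, limma adjusted p = 0.000657). A region at an end of Ttn (chromosome 2, 76981400 to 76982399), the gene of the giant sarcomere protein titin, held no reads in either rtTA library and 7.30 ± 3.83 RPM with Myod1, at least 10.7-fold higher (6.7-fold from the lower Myod1 library, at 4.59 RPM). Mymk, which encodes the myoblast fusion protein myomaker, rose from 0.545 ± 0.771 to 9.98 ± 1.73 RPM (chromosome 2, 27071659 to 27072658).

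The muscle list stood 0.64 above the median of all regions with Myod1 (camera adjusted p = 0.00108, and adjusted p = 0.631 with an estimated correlation). Without regions near gene ends the call was lost (adjusted p = 0.145). In rtTA against no virus, 8 regions of the list were higher. Against no virus, 51 of its regions and 37 of its genes were higher with Myod1, 0.48 above the median of all regions (camera adjusted p = 0.00141, and adjusted p = 0.935 with an estimated correlation). Of the 18 myogenic regulators, 9 rose, 2 fell and 4 were mixed (23 regions of 59 higher and 7 lower, with the same counts adjusted over the list alone; camera adjusted p = 0.195). Vgll2, a cofactor of muscle transcription, rose from 0.245 ± 0.346 to 7.28 ± 0.106 RPM. Mef2d rose from 1.85 ± 1.33 to 17.3 ± 1.26 RPM and Mef2a from 1.60 ± 0.983 to 13.1 ± 0.474 RPM.

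Neuronal genes were also among those that rose with Myod1, where 30.8% of all regions were higher than with rtTA. Of 39 genes of neuronal structure and synapse, 21 rose, 3 fell and 3 were mixed (46 regions of 112 higher and 7 lower, and 44 and 7 adjusted over the list alone). Stmn4 went from 1.06 ± 0.212 to 14.3 ± 3.05 RPM (chromosome 14, 66340919 to 66341918), Cplx2 from 0.680 ± 0.962 to 10.1 ± 2.98 RPM and Syt1 from 0.470 ± 0.0283 to 9.47 ± 3.38 RPM. The proneural regulator Zbtb18 rose from 0.710 ± 0.368 to 22.5 ± 7.55 RPM in its gene body (chromosome 1, 177444116 to 177445115; log2 fold change 3.76, SE 0.35, limma adjusted p = 0.000657; 2.29 against no virus). As a list, the neuronal genes stood 0.32 above the median of all regions without passing the threshold (camera adjusted p = 0.0643), and against no virus they stood 0.04 above it (adjusted p = 0.687). For Myod1 over rtTA the camera adjusted p was 0.00954 with 1 region per gene and 0.624 with an estimated correlation. Of 27 proneural regulators, 12 rose, 4 fell and 5 were mixed (43 regions of 126 higher and 15 lower, and 41 and 14 adjusted over the list alone; camera adjusted p = 0.603). After centring, 28 proneural regions were higher and 25 lower, with 6 genes risen, 8 fallen and 8 mixed. In rtTA against no virus, 6 regions of the neuronal list and 22 of the proneural list were higher. There the neuronal list stood 0.28 below the median of all regions (camera adjusted p = 0.00709, and adjusted p = 0.257 with an estimated correlation). The 0.32 with Myod1 was thus measured against a control that was relatively low at this list. With Myod1 over no virus, 34 of 112 neuronal regions and 31% of all regions were higher.

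Fibroblast and ubiquitously used genes were among those that fell with Myod1, where 20.5% of all regions were lower and 30.8% higher than with rtTA. Vim and Fbn1, given below, fell at regions that were high in the rtTA libraries. Of 44 fibroblast genes, 17 fell, 11 rose and 5 were mixed (36 regions of 190 lower and 37 higher, and 34 and 37 adjusted over the list alone; camera adjusted p = 0.407). Centring turned these to 57 lower and 18 higher. In rtTA against no virus 28 of the 190 fibroblast regions were higher, and 20.6% of all regions. Vim, the gene of the intermediate filament vimentin, fell from 50.6 ± 9.21 to 2.20 ± 1.24 RPM at its end (chromosome 2, 13574061 to 13575060) and held 5.48 ± 0.453 RPM without virus. Fbn1, the gene of the matrix protein fibrillin, fell from 33.9 ± 11.6 to 0.395 ± 0.375 RPM and held 0.955 ± 0.219 RPM without virus. Of 18 ubiquitously used genes, 11 fell and 2 were mixed (17 regions of 33 lower and 3 higher, and 17 and 4 adjusted over the list alone). Their median was 1.08 below that of all regions (camera adjusted p = 0.000592, adjusted p = 0.631 with an estimated correlation, and adjusted p = 0.0777 without regions near gene ends). Against no virus their median was 0.29 below that of all regions (camera adjusted p = 0.0137, and adjusted p = 0.935 with an estimated correlation), with 5 regions higher and 1 lower. Of these 33 regions, 18 were higher in rtTA than without virus. Of the 46 named falls, 3 also fell against no virus, namely Dlk1, Cnn2 and Actb, with log2 fold changes of -1.69, -1.62 and -1.66. In the Notch pathway, 7 of 23 genes fell, 4 rose and 7 were mixed (18 regions of 96 lower and 23 higher, with the same counts adjusted over the list alone, and 24 lower and 18 higher after centring; camera adjusted p = 0.851), including Hes1 with a log2 fold change of -3.88 against rtTA and -0.59 against no virus (adjusted p = 0.468).

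In limma, 7892 regions were higher and 5255 lower with Myod1 than with rtTA alone, with a median log2 fold change of 0.26 over all regions. Against no virus, 124 regions were lower and 7941 higher as deposited, 2727 and 1371 after centring, and 1554 and 2137 after quantile normalization. Of the 5255 regions lower than with rtTA, 3098 lay within 1 kb of a gene end. The share of calls that were higher was 60% as deposited, 41.0% after centring (which lowers every log2 fold change by 0.35) and 52.6% after quantile normalization, and 8420 regions were called without rtTA replicate 1. Of the 32 named rises, 31 stayed past the threshold after centring and 29 also rose against no virus, the exceptions being Cldn5, Krt8 and Mef2c.

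Regions higher with both factors were counted to ask how far the acetylation gained with Myod1 coincides with that gained with Ascl1. With both factors, 5944 regions were higher than with rtTA, which is 75.3% of the regions that rose with Myod1, and independent lists of these sizes share 3615. Of 46 neuronal regions that rose with Myod1, 42 rose with Ascl1, and 31 of these did not differ between the factors in limma. Of 54 muscle regions that rose with Myod1, 38 rose with Ascl1. Of the other 16, 10 were higher with Myod1 than with Ascl1 in the direct comparison. Zbtb18, Stmn4, Syt1, Cplx2, Olfml2b, Mef2a and Mef2d were raised by both factors at the same regions. Of the shared regions 58.2% lay in gene bodies, 38.2% between genes and 3.5% at gene ends, against 50.2%, 29.8% and 19.9% of the tested regions. Gene ends are where the rtTA libraries themselves were high. Of the 5944 regions, 965 were higher with Ascl1 than with Myod1 and 227 were higher with Myod1.

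Both comparisons use the same rtTA libraries, which by itself makes their fold changes correlate. The fold changes correlated across regions at Pearson's r = 0.71 (Spearman's rho = 0.65), and simulated groups without any change that shared the control libraries gave 0.50 on average in 20 simulations. The covariance of the fold changes was 1 and averaged 0.07 in the simulations. The simulated groups differ by replicate noise only. They therefore cannot show what a feature common to both rtTA libraries, such as their high signal at gene ends, adds to either value. With Ascl1 against rtTA and Myod1 against no virus, 5466 regions were higher with both (3638 for independent lists; r = 0.45). With Ascl1 against no virus and Myod1 against rtTA the count was 5581 (5530 for independent lists; r = -0.05). Against no virus as well as rtTA, 4351 regions were higher with both factors. Centring left 1736 shared regions (673 for independent lists), quantile normalization left 1881, and 3832 were shared without rtTA replicate 1.

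**Figure D3:**
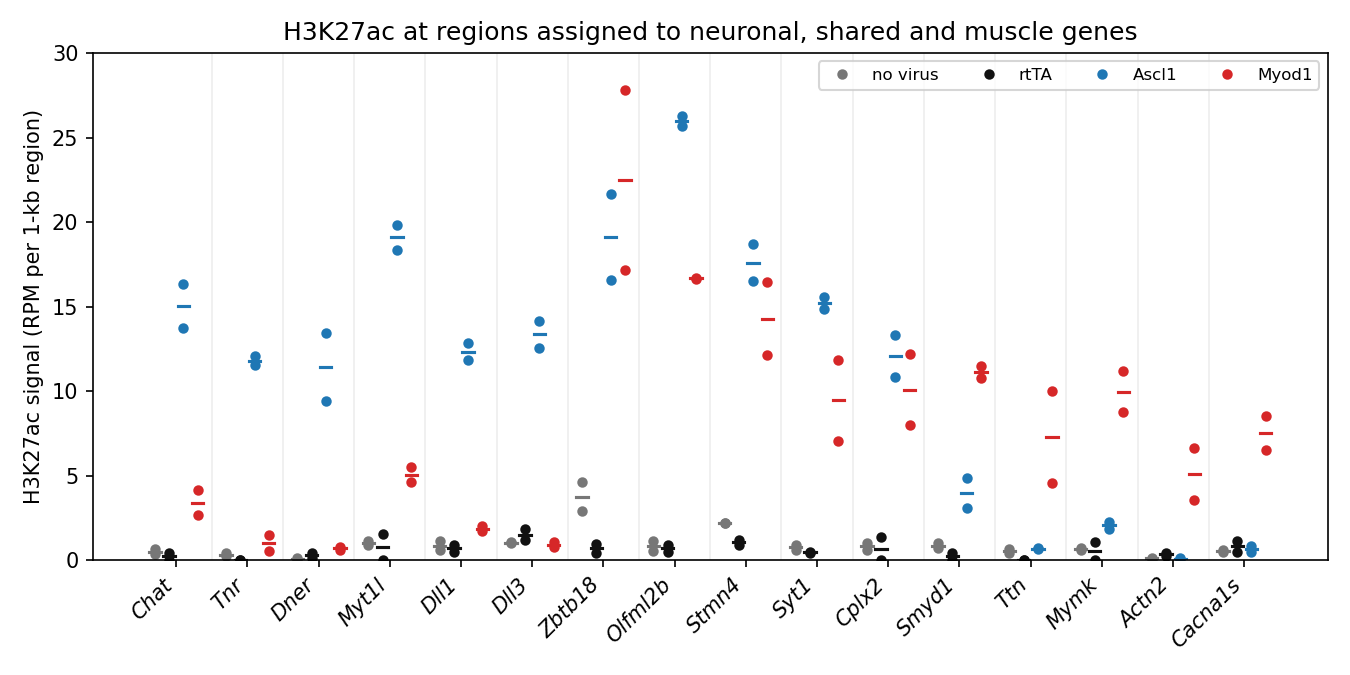
H3K27ac signal (y axis, RPM per region of 1 kb) in each library at 16 regions, 1 per named gene, with points for the 2 libraries of a group and a bar for their mean. Regions of Chat, Tnr, Dner, Myt1l, Dll1 and Dll3 were highest with Ascl1, those of Zbtb18, Olfml2b, Stmn4, Syt1 and Cplx2 were high with both factors, and those of Smyd1, Ttn, Mymk, Actn2 and Cacna1s were highest with Myod1.

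Ascl1 and Myod1 were compared directly to find the regions that tell the factors apart. The fold changes use no control libraries, but the spread behind the p-values was estimated from all 8 libraries. With the libraries of these 2 groups alone, 6495 regions were called, against 11499 with all libraries. Muscle genes with more acetylation with Myod1 included Actn2, 21.1 kb from the region (chromosome 13, 12361288 to 12362287), at 5.08 ± 2.18 RPM against 0.095 ± 0.0212 RPM with Ascl1 (log2 fold change of Ascl1 over Myod1 -2.43, SE 0.32, limma adjusted p = 0.00121). The calcium channel gene Cacna1s held 7.52 ± 1.46 RPM with Myod1 and 0.670 ± 0.283 RPM with Ascl1, and Ttn 7.30 ± 3.83 and 0.675 ± 0.0354 RPM. The RNA-binding myogenic regulator Rbm24 held 3.96 ± 0.502 and 0.405 ± 0.191 RPM. The genes with the largest differences in favour of Myod1 were Epn2 (17.5 ± 5.68 against 1.18 ± 0.205 RPM), Psmg2 (16.3 ± 4.52 against 1.11 ± 0.580 RPM), Cwf19l1, Cystm1, Ccdc192, Ufc1, Cyfip1 and Cep192, with log2 fold changes from -3.06 to -2.65.

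Neuronal genes with more acetylation with Ascl1 included Rbfox3, the gene of the neuronal nuclear marker NeuN, at 10.6 ± 1.63 RPM against 0.490 ± 0.509 RPM with Myod1 (chromosome 11, 118752059 to 118753058; log2 fold change 2.99, SE 0.36, limma adjusted p = 0.00114). Dner held 11.4 ± 2.85 and 0.695 ± 0.148 RPM, the adhesion gene Dscam 6.75 ± 0.735 and 0.395 ± 0.375 RPM, and Bcl11a 11.1 ± 0.785 and 0.330 ± 0.0849 RPM. The Notch ligand gene Dll3 held 13.4 ± 1.12 RPM with Ascl1 and 0.925 ± 0.177 RPM with Myod1. Largest of all were the differences at Plxna2, Pofut2, Lrrc20, Sh3rf3, Slc25a48, Irs1, Nuak1 and Srrm3, as the rule names them. Pofut2 held 13.1 ± 2.47 against 0.330 ± 0.0990 RPM and Srrm3 13.5 ± 1.29 against 0.495 ± 0.332 RPM. At the end of Plxna2 the Ascl1 libraries held 18.2 ± 22.5 RPM, a spread wider than the mean.

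Of the 53 muscle genes, 13 were higher with Myod1, 15 with Ascl1 and 4 were mixed (17 regions of 101 and 26, and 17 and 25 adjusted over the list alone), which centring turned to 29 regions in favour of Myod1 and 4 of Ascl1. Their median was 0.41 in favour of Ascl1 and 0.26 below that of all regions, so camera placed the list towards Myod1 (adjusted p = 0.0373, and adjusted p = 0.892 with an estimated correlation). That call was lost without regions near gene ends (adjusted p = 0.485), with 1 region per gene (adjusted p = 0.0528) and at equal depth (adjusted p = 0.0541). Of 27 proneural regulators, 21 were higher with Ascl1, 1 with Myod1 and 3 were mixed (75 regions of 126 and 5, and 80 and 5 adjusted over the list alone). This list stood 0.51 above the median of all regions (camera adjusted p = 0.0474, and adjusted p = 0.892 with an estimated correlation), a call lost without Myod1 replicate 1 (adjusted p = 0.164). It was also lost with 1 region per gene (adjusted p = 0.582), with regions within 10 kb (adjusted p = 0.113) and at equal depth (adjusted p = 0.0541). Of 39 neuronal genes, 27 were higher with Ascl1, 1 with Myod1 and 1 was mixed (56 regions of 112 and 2, and 58 and 2 adjusted over the list alone; camera adjusted p = 0.0672). Of 18 myogenic regulators, 10 were higher with Ascl1, 3 with Myod1 and 2 were mixed (15 regions of 59 and 5, and 14 and 5 adjusted over the list alone; camera adjusted p = 0.351), which centring turned to 3 and 11. Fibroblast genes were higher with Ascl1 at 25 of 44 genes (79 regions of 190 higher and 8 lower, and 82 and 8 adjusted over the list alone; camera adjusted p = 0.575). Notch pathway genes were higher at 16 of 23, with 40 regions of 96 higher and 4 lower (camera adjusted p = 0.592). Adjusted over the list alone, the Notch counts were 41 and 4. Centring left 25 fibroblast regions higher and 17 lower, and 16 and 11 Notch regions. It left 32 and 9 proneural regions and 25 and 12 neuronal ones.

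In limma, 9867 regions were higher with Ascl1 and 1632 with Myod1, with a median log2 fold change of 0.66. The share of calls in favour of Ascl1 was 85.8% as deposited, 46.0% after centring (which lowers every log2 fold change by 0.69) and 47.4% after quantile normalization, and 3283 regions favoured Ascl1 and 1632 Myod1 in all 3 scalings. Without Ascl1 replicate 1 there were 6204 calls and without Myod1 replicate 2 there were 5236.

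The controls were compared with each other to measure the level of change without either factor. Acetylation was higher in rtTA mainly at the ends of genes. Rbbp6 held 44.1 ± 12.6 RPM with rtTA and 0.130 ± 0.0141 RPM without virus at a region over its end (chromosome 7, 122969660 to 122970659; log2 fold change 5.29, SE 0.81, limma adjusted p = 0.00409). 1810013L24Rik held 48.6 ± 22.6 against 0.265 ± 0.0212 RPM and Irf2bp2 38.7 ± 17.6 against 0.035 ± 0.0495 RPM. Lower in rtTA were Layn (0.605 ± 0.856 against 3.30 ± 0.389 RPM), Inpp4b (1.13 ± 0.636 against 4.86 ± 0.721 RPM) and Zbtb18 (0.710 ± 0.368 against 3.76 ± 1.23 RPM). Of 18 ubiquitously used genes, 14 were higher with rtTA (18 regions of 33, and 19 adjusted over the list alone), 0.78 above the median of all regions (camera adjusted p = 0.00103, and adjusted p = 0.976 with an estimated correlation). The call was lost without regions near gene ends (adjusted p = 0.144), with regions within 10 kb (adjusted p = 0.0533) and with 1 region per gene (adjusted p = 0.106). Of 39 neuronal genes, 5 were higher with rtTA and 1 lower (6 regions of 112 and 1; adjusted over the list alone 5 were higher and the lower one did not pass), and the list stood 0.28 below the median of all regions (camera adjusted p = 0.00709, and adjusted p = 0.257 with an estimated correlation). The neuronal call was lost with regions within 10 kb (adjusted p = 0.0533) and without regions near gene ends (adjusted p = 0.170).

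In limma, 5294 regions were higher and 79 lower in rtTA than without virus. Centring gave 3665 higher and 1113 lower, and quantile normalization 1783 and 653. Of the regions within 1 kb of a gene end, 65.1% were higher (50.4% after centring), against 11.9% in gene bodies and 5.7% between genes. Calls were lost without any 1 of these libraries, while the fold changes of all regions correlated at 0.96 to 0.98 with those from all libraries. Without no-virus replicate 1 limma called 0 regions (5430 at an unadjusted p under 0.05, and 0 by edgeR), and without rtTA replicate 1 it called 0 (5884 at an unadjusted p under 0.05, and 0 by edgeR). Without no-virus replicate 2 it called 2207, and without rtTA replicate 2 it called 3958. The 6 genes named here lost their calls without no-virus replicate 1 or without rtTA replicate 1, where Rbbp6 stood at log2 fold changes of 5.30 (SE 1.09, adjusted p = 0.0597) and 5.00 (SE 1.12, adjusted p = 0.0851). With all libraries its SE was 0.81, and it kept its call at SE 1.09 without no-virus replicate 2 (adjusted p = 0.0438), so the SE alone did not decide. Irf2bp2 stood at 5.24 and 4.72 and 1810013L24Rik at 5.23 and 4.73. Layn, Inpp4b and Zbtb18 also lost their calls without no-virus replicate 2. Their log2 fold changes there were -1.44, -1.36 and -1.2, against -1.53, -1.49 and -1.47 with all libraries. They were -1.62, -1.61 and -1.74 without no-virus replicate 1, and -0.96, -1.18 and -1.25 without rtTA replicate 1.

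Regions assigned to the genes of the factors themselves were read in every group, among the tested regions only. The nearest region to Ascl1 (chromosome 10, 87494393 to 87495392, 1.23 kb away) held 6.70 ± 2.04 RPM with Ascl1, 0.465 ± 0.276 RPM with Myod1, 0.455 ± 0.643 RPM with rtTA and 0.615 ± 0.177 RPM without virus. Its log2 fold change with Ascl1 over rtTA was 2.45 (SE 0.37, limma adjusted p = 0.000491). A region 27.4 kb from Myod1 (chromosome 7, 46348584 to 46349583) held 1.74 ± 0.537 RPM with Ascl1, 1.88 ± 0.714 RPM with Myod1, 0.470 ± 0.0283 RPM with rtTA and 0.165 ± 0.0636 RPM without virus. The Myod1 region passed the threshold as deposited with both factors (limma adjusted p = 0.0324 and 0.0235) and not after centring, where the log2 fold change with Ascl1 turned to -0.16. It lost its call with Ascl1 without Ascl1 replicate 1 (adjusted p = 0.137), with Myod1 without Myod1 replicate 2 (adjusted p = 0.131), and with either factor without either rtTA library, where its fold change stayed at 0.86 and 0.90 with Ascl1 (0.88 with all libraries) and at 0.93 and 0.97 with Myod1 (0.95). Another region assigned to Myod1, which ends at position 46366463 of chromosome 7, lies nearer to that gene, and its values are not given here. The region numbers skip 5 values in the table, 1 next to Ascl1, 3 next to Myod1 and 1 on an unplaced scaffold, and regions over the genes themselves were not analysed here.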

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

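Alternatives chosen after seeing the data were assignment by the nearer gene end, edgeR with the deposited totals, leaving out gene-end regions, equal depth, quantile normalization and edgeR for the shared regions, calls against both controls, the alternatives for lists other than muscle, neuronal and fibroblast genes, and edgeR without single libraries; in the values below, the cause of a change was not tested unless named. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups. With the replicate number as a term (replicate block), 13528, 13454, 12152 and 5840 regions were called in Ascl1 against rtTA, Myod1 against rtTA, Ascl1 against Myod1 and rtTA against no virus, and 6030 were higher with both factors. The replicate block gave adjusted p values of 0.00116 for muscle genes with Myod1, 1.45e-05 and 0.0641 for neuronal genes with Ascl1 and Myod1, and 0.679 and 0.438 for fibroblast genes. Residuals of equal replicate numbers correlated between -0.15 and 0.29 across group pairs, so the numbers were not taken to pair the samples.

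For Ascl1 against rtTA, 20 of 23 alternatives stayed within 1.5 times the 12822 calls. Quantile normalization gave 7234, a test against 1.5-fold 6749 (a stricter hypothesis by construction), DESeq2 8317 (3559 higher and 4758 lower), no virus as control 18067, and leaving out 1 library 9102 to 12477. The main direction turned with DESeq2, with edgeR and TMM (3589 higher and 5046 lower) and after centring. For Myod1 against rtTA, 18 of 23 stayed within 1.5 times 13147. The test against 1.5-fold gave 6643, no virus as control 8065, all 4 control libraries together 7619, calls also made against no virus 6278, and leaving out 1 library 8420 to 12101. Here too the main direction turned with edgeR and TMM (5361 higher and 6090 lower), with DESeq2 (5075 higher and 6012 lower) and after centring. For Ascl1 against Myod1, 14 of 20 stayed within 1.5 times 11499. Only these 2 groups gave 6495, 1.5-fold 3606, edgeR with TMM 6790 (3282 higher and 3508 lower), DESeq2 6733, and leaving out 1 library 5236 to 10955. For rtTA against no virus, 13 of 20 stayed within 1.5 times 5373. Quantile normalization gave 2436, no gene-end regions 1796 (fewer regions by construction), 1.5-fold 2581, edgeR with TMM 3516, and leaving out 1 library 0 to 3958, with no call without no-virus replicate 1 or rtTA replicate 1. Regions higher with both factors numbered 1736 after centring, 1881 after quantile normalization, 2102 with edgeR and TMM, and 3832 to 5476 without 1 library, against 5944.

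Lists were called with the preset correlation only. With an estimated correlation, muscle genes with Myod1 had a camera adjusted p of 0.631, and neuronal genes 0.0634 with Ascl1 and 0.624 with Myod1. The estimated correlations were 0.004 for neuronal, 0.064 for muscle, 0.095 for proneural and 0.142 for ubiquitously used genes. For neuronal genes the estimate lies under the preset 0.01, so a higher correlation between regions is not what cost their call with Ascl1. Muscle genes with Myod1 also lost the call over 1 kb from gene ends (0.145), while leaving out 1 library gave 0.00163 to 0.00248. Neuronal genes with Myod1 passed with 1 region per gene (0.00954), and without 1 library ranged from 0.0298 to 0.125. Fibroblast genes with Myod1 passed against no virus (0.0137), low only relative to all regions, since 39 of their regions were higher and 4 lower. Fibroblast genes with Ascl1 ranged from 0.118 to 0.794 without 1 library and turned upward without Ascl1 replicate 1.

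Over the alternatives of the named regions, 4843 of 5217 values kept direction and side of the threshold, 348 lost the call and 26 turned. Most named regions were chosen for their large changes in the same data, so these counts do not hold for all regions. For the other called lists, 65 of 87 kept the call and 22 lost it. With no virus as control, the log2 fold changes of the falls with Ascl1 turned to 1.99 at Irs2, 2.18 at Irf2bp2, 2.16 at Gas1, 2.40 at Rbbp6, 1.87 at Ywhaz, 2.13 at Fasn, 2.41 at 1810013L24Rik, 2.15 at Rmi1, 1.29 at Cebpb, 1.61 at Ubc, 2.28 at Hspa8 and 1.55 at Rplp0, of which those at Irs2, Gas1, Ywhaz, Fasn and Cebpb did not pass the threshold (adjusted p from 0.0529 to 0.112). With the 4 control libraries together, Hspa8 stood at 0.32 and Rplp0 at 0.01. With Myod1 and no virus as control, the log2 fold change was 0.03 at 1810013L24Rik and Dlx2, 0.01 at Gas1, 0.04 at Irf2bp2, 0.23 at Notch1, 0.13 at Cdkn1b and Cebpb, 0.18 at Tap1, 0.16 at Fli1 and 0.33 at Myl3. The region near Myod1 stood at -0.16 with Ascl1 after centring, with and without the replicate block. The GC correction with the replicate block, the input correction, IP over input and the E-box tests were not run, as neither genome sequence nor input values were used here. Depth limits the rtTA libraries most, where 1 read is 0.2274 and 0.1213 RPM.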

Other observations

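Every test of an explanation in this part was chosen after the result was seen, while the camera tests of all lists in the 4 main comparisons were planned; the test of enrichment replaced an earlier one on the share of calls that were higher after centring (30.5%), and the test of the share of reads replaced one that used the same control libraries for both factors (1736 shared regions).

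Some markers of other cell types gained acetylation with Ascl1, though no list in this paragraph passed camera and 45.8% of all regions were higher. A gene-body region of the calcium channel gene Ryr2 (chromosome 13, 11959223 to 11960222) went from 0.820 ± 0.127 to 18.7 ± 0.530 RPM (SD, n = 2; limma adjusted p = 0.000178), and 8 of 11 heart regulators rose (14 regions, and 15 adjusted over the list alone; camera adjusted p = 0.208). A region 58.3 kb from Mycn went from 0.605 ± 0.856 to 11 ± 0.622 RPM, and 10 of 27 cell cycle genes rose, 3 fell and 2 were mixed (42 regions higher and 5 lower, and 41 and 4 adjusted over the list alone; 0.419). Endothelial genes rose at 9 of 12 (19 regions, and 19 adjusted over the list alone; 0.202), including Cldn5 with a log2 fold change of 3.07, and epithelial genes at 6 of 7 (8 regions, and 8 adjusted over the list alone; 0.222). Smooth muscle and actin genes rose at 9 of 16 and 1 fell (21 and 1 regions, and 21 and 1 adjusted over the list alone; 0.604), cartilage, bone and fat genes rose at 8 of 13, 1 fell and 1 was mixed (23 and 4, and 23 and 4 adjusted over the list alone; 0.604), and glia and neural crest genes rose at 4 of 10 and 1 fell (14 and 1, and 15 and 1 adjusted over the list alone; 0.419). Interferon genes rose at 4 of 12 and 1 fell (4 and 1, and 4 and 1 adjusted over the list alone; 0.186), and macrophage and blood genes rose at 5 of 9 (9 regions, and 9 adjusted over the list alone; 0.921). After centring, more regions were lower than higher in the smooth muscle (22 and 6), cell cycle (37 and 6), interferon (9 and 1), macrophage (6 and 1) and cartilage (15 and 4) lists. Between the controls, 8 smooth muscle, 31 cell cycle, 7 interferon, 3 macrophage, 5 endothelial, 1 epithelial, 11 cartilage, 2 glia and 2 heart regions were higher in rtTA and none lower, with camera adjusted p values from 0.101 for interferon genes to 0.958.

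With Myod1 against rtTA the same lists moved both ways as deposited, and none passed camera. After centring, more regions were lower than higher in the cell cycle (40 and 13), smooth muscle (23 and 7) and cartilage (15 and 3) lists. The same held for interferon (8 and 2), macrophage (8 and 3) and endothelial genes (7 and 4). Glia genes had 7 higher and 6 lower, heart genes 5 and 5, and epithelial genes 2 and 2. The counts that follow against rtTA are as deposited. Cell cycle genes fell at 13 of 27, rose at 4 and were mixed at 6 (25 regions lower and 23 higher, as adjusted over the list alone; camera adjusted p = 0.195), with Aurka at 1.78 ± 1.38 RPM against 29.9 ± 7.18 RPM in rtTA and 3.54 ± 0.226 RPM without virus (n = 2). A region 1.19 kb from the actin-binding gene Synpo2 rose from 1.18 ± 0.389 to 15.6 ± 2.25 RPM, and of 16 smooth muscle genes 3 rose, 5 fell and 5 were mixed (15 regions higher and 16 lower, and 15 and 17 adjusted over the list alone; 0.407). Counts of regions higher and lower were 3 and 5 for interferon (0.308), 8 and 4 for endothelial (0.968), 3 and 1 for epithelial (0.929), 13 and 12 for cartilage (0.765) and 6 and 3 for heart genes (0.724), all as adjusted over the list alone, 5 and 3 for macrophage genes (3 and 1 adjusted over the list alone; 0.777) and 10 and 3 for glia genes (9 and 3 adjusted over the list alone; 0.724). Ascl1 exceeded Myod1 at 24 smooth muscle, 48 cell cycle, 7 interferon, 9 macrophage, 18 endothelial, 6 epithelial, 22 cartilage, 14 glia, 8 heart and 14 ubiquitous regions. In the same order Ascl1 fell below Myod1 at 2, 5, 1, 0, 0, 0, 4, 4, 1 and 1. Adjusted over the list alone, 23, 48, 7, 7, 18, 6, 22, 14, 8 and 15 were higher. Camera adjusted p ran from 0.127 to 0.828. Centring gave 11 higher and 5 lower for smooth muscle, 18 and 15 for cell cycle, 9 and 8 for cartilage and 6 and 5 for glia genes. It gave 4 and 3 for interferon, 2 and 1 for macrophage, 8 and 1 for endothelial and 4 and 2 for epithelial genes. For heart and ubiquitous genes it gave 5 and 4, and 8 and 1. Against no virus, Myod1 left fibroblast genes 0.23 and smooth muscle genes 0.26 below the median of all regions, with medians of 0.35 and 0.32 themselves and more regions higher (39 and 18) than lower (4 and 2) (both camera adjusted p = 0.0137, and adjusted p = 0.935 and 0.962 with an estimated correlation), and myogenic regulators 0.31 above it (adjusted p = 0.0448, and adjusted p = 0.935 with an estimated correlation). Median and mean differed in sign with Myod1 against rtTA for fibroblast (0.11 and -0.13), macrophage (-0.08 and 0.01) and cartilage genes (0.29 and -0.15). The median relative to all regions and the direction of camera differed with Ascl1 for macrophage (-0.10, upward) and cartilage genes (0.01, downward), and with Myod1 for proneural (-0.07, upward), endothelial (-0.07, upward), epithelial (-0.18, upward) and cartilage genes (0.03, downward). They also differed between the factors for fibroblast (-0.02, upward) and smooth muscle genes (-0.15, upward), and between the controls for smooth muscle (0.01, downward) and epithelial genes (0.11, downward).

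H3K27ac at gene ends was higher in rtTA than without virus at 65.1% of 5102 regions. Counting noise from unequal depth is argued against, since 61.9% were still called with all libraries thinned to the shallowest. Thinning keeps the expected RPM of each region, so other traits tied to depth were not tested. An effect of the rtTA virus and doxycycline alike in all cells that carry them is argued against by the Myod1 libraries, which were higher than no virus at 12% of these regions, while the Ascl1 libraries were higher at 69% of them and at 70.6% of regions in gene bodies. A loss of gene-end reads without virus to below the level elsewhere is argued against for the regions as a whole, since 4.3% of those higher in rtTA lay under it (2.8% between genes, 2.1% in gene bodies), but Rbbp6, 1810013L24Rik and Irf2bp2 lay under it and for them it stays open. A partial gain or loss of gene-end reads in preparation, such as GC bias, a batch difference and an effect of rtTA that differs between the induced cells stay open.

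More regions were higher with both factors than independent lists give. How much of this comes from a higher share of reads in the regions, from the shared rtTA libraries or from a true overlap cannot be told apart. After centring and with separate controls, 550 regions were higher with both against 181 for independent lists (Ascl1 against rtTA) and 495 against 303 (Ascl1 against no virus), ratios of 3.04 and 1.63, but the second ratio fell to 0.61 without Ascl1 replicate 2. Away from gene ends, the fold changes correlated at 0.37 with Ascl1 against rtTA and Myod1 against no virus, and at -0.01 with the controls exchanged. These pairings differ too much from each other to decide.

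The median log2 fold change of all regions with Ascl1 against rtTA was 0.77, and 45.8% of regions were called higher. Counting noise from unequal depth is argued against, since the median was 0.76 at equal depth. As thinning keeps the expected RPM of each region, it cannot decide on other traits tied to depth. Also argued against is that a few of these regions took most of the reads of the control libraries. The 1% of regions with the most reads held at most 6.6% of the reads in the regions in any library. Sites outside the regions could not be tested in this way. RPM is scaled to the total reads of each library, so an even rise over the whole genome would not raise it. The level outside the regions was 0.269 and 0.286 RPM per kb with Ascl1, and 0.3 and 0.311 with rtTA. Without virus it was 0.339 and 0.335. Better enrichment of the Ascl1 immunoprecipitates, a rise at acetylated sites in general and a gain confined to these regions stay open. They cannot be told apart with the values used here, which hold no spike-in. How the regions were chosen is not known, and a choice by peaks of the 2 factors would favour rises with them. Median fold changes at gene ends, in gene bodies and between genes differed by 0.03 against no virus and by 1.48 against rtTA (-0.38, 0.92 and 1.10). The first value averages libraries that went apart, with 1.64, 1.36 and 1.32 in replicate 1 and 0.80, 1.18 and 1.22 in replicate 2.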
